A study of Mus musculus with 8 samples.

How the data were processed

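RNA was measured by sequencing in 8 libraries of mouse spleen CD4 T cells. The cells came from dual reporter mice in which green fluorescence marked KLF2 and red fluorescence marked FOXP3. FOXP3-negative CD44hi cells were sorted as KLF2-positive (KLF2+) or KLF2-negative (KLF2-). Both populations were kept for 48 h with no stimulus, or with 2.5 micrograms/mL of anti-CD3 and 1.25 micrograms/mL of anti-CD28, which together engage the T cell receptor and a costimulatory receptor. This gave 4 groups of 2 libraries. The labels number the KLF2+ libraries 1 and 2 and the KLF2- libraries 3 and 4. The titles name polyA RNA, and the library kit named in the labels was the SMARTer stranded pico kit. How these fit together was not given in the sources used here.

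Per the file headers, the authors counted reads over exons with HOMER's mm10 RefSeq annotation, with no adjustment for depth, which gives estimated counts: every value is a multiple of 0.5. The submitters' processing notes name STAR 2.7.9 for alignment, HOMER 4.11, SAMtools and DESeq2. The read filters and the treatment of strand were not given in the sources used here. A second deposited table holds TPM, transcripts scaled to a common sum, for the same libraries, and it was used for the limma alternatives only. The table holds 25124 genes, 1 row per gene, with exon coordinates of the mouse build mm10. The estimated counts were rounded to whole numbers before the count models were fitted.

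Genes were kept by edgeR's filterByExpr over the 4 groups, which left 19146. All 8 libraries were fitted together in edgeR 4.0.16 (R 4.3.3) with TMM scaling and 1 coefficient per group, leaving 4 residual degrees of freedom. Contrasts were tested with the quasi-likelihood F test, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested. Genes with an adjusted p under 0.05 were called. Counts of list members that were higher, lower, positive or negative, or that rose or fell, are counts of called genes. There were 4 contrasts between groups, KLF2+ against KLF2- without and with stimulus, and stimulated against unstimulated in each population. The fifth was the difference between the responses of the populations. Standard errors were the absolute log2 fold change divided by the square root of F. Levels are CPM, counts scaled to a common depth with TMM factors. The labels do not say that the replicates are separate animals or cultures, so the p-values measure the spread between these samples, which may be technical.

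Before the data were examined, 31 gene lists with 626 genes were fixed, of which 621 were in the table and 602 were tested. They were T cell identity, KLF2-linked trafficking, resting and central memory, Treg identity, suppressive effector molecules, the TGF-beta pathway, Tfh, Th1, Th2, Th17, cytokines, inhibitory receptors and exhaustion, cytotoxic, TCR-induced early response, S phase, G2/M phase, glycolysis, amino acid and one-carbon metabolism, cholesterol synthesis, oxidative phosphorylation, ribosome biogenesis, interferon-stimulated genes, p53 and apoptosis, the unfolded protein response, replication-dependent histones, and dissociation and heat-shock stress. Markers of B cells, myeloid cells, CD8 T cells, NK and innate-like T cells, and erythroid cells and platelets were listed as other cell types. A list of at least 3 tested genes was tested as a set by camera (limma 3.58.1) with the preset correlation of 0.01, over 30 lists. Camera with an estimated correlation and fry were run beside it.

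The genes named in the text followed a rule also fixed then. It took the 5 genes with the largest and the 5 with the smallest log2 fold change among called genes with a mean of at least 10 CPM and both libraries of one group above both of the other. Gene models without a name of their own, small RNA genes and histone genes were passed over. In each list described, up to 4 called members with the smallest p were taken, or the most abundant member where none was called. Among the genes always read were Klf2, Foxp3, Cd4, Cd44, S1pr1, Tgfb1, Il10, Ifng, Il17a, Il4 and Il2. Some genes that the rule took are not reported here. For the difference in response, the 5 largest and 5 smallest called values were taken without the rule on libraries.

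Background reads were measured over 1464 olfactory and vomeronasal receptor genes (1683.9 kb of exons), which T cells are not known to express. Their reads per kb in a library gave a density that was multiplied by each gene's exon length and subtracted. TMM factors were then taken from genes of at least 50 CPM, and this background-corrected fit tested 15292 genes. It was added after the data were seen, as were scaling from genes of at least 50 CPM alone, subtraction of 2 times the background, and fits without replicate 4 of the stimulated KLF2- group. A fit with a term for a trait read from the expression values themselves was also run and then left out, since samples were not to be grouped by what was measured in them. The alternatives planned beforehand were edgeR's RLE factors, DESeq2 1.42.0, no filter, a filter of 5 CPM in 2 libraries, limma on log2 TPM with a pseudocount of 1 or 0.1, the 4 libraries of a comparison alone, a replicate block, and leaving out each library in turn.

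Depth was 2.99 M to 36.6 M exon reads per library (M, mega). The pipeline was tested on simulated counts of the same depths in which 100 genes were changed 2-fold and 100 were changed 4-fold in each contrast. For KLF2+ against KLF2- without stimulus, 12 of the 2-fold and 62 of the 4-fold changes were recovered among 18111 genes. For the stimulated comparison 12 and 53 were recovered among 18092 genes. For the response of KLF2+ cells 14 and 62 were recovered among 18106 genes, and for KLF2- cells 12 and 57 among 18129. For the difference in response 9 and 30 were recovered among 18079. In a second simulation with equal expression in all libraries and the measured background added, 22942 genes entered the fit. The uncorrected fit called 0 genes without stimulus, 14085 with stimulus, 4922 for the KLF2+ response, 0 for the KLF2- response and 5377 for the difference in response. After correction, 0 of 13601 genes were called in any of the 5. Counts of 0 here are from edgeR on simulated values.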

Results

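Spleen CD4 T cells that were FOXP3-negative and CD44hi, the surface state of activated and memory cells, were compared by KLF2 reporter level. KLF2 is a transcription factor of resting T cells that drives genes for exit from lymphoid tissue. The 4 groups were unstimulated KLF2+, stimulated KLF2+, unstimulated KLF2- and stimulated KLF2- cells, each with 2 libraries. Libraries held 33.9 M to 45.6 M aligned tags (M, mega). Reads over exons numbered 8.27 M and 17.8 M in unstimulated KLF2+ cells, 21.03 M and 36.6 M in stimulated KLF2+ cells, 7.34 M and 8.62 M in unstimulated KLF2- cells, and 4.53 M and 2.99 M in stimulated KLF2- cells. The share of tags in exons was 71.2% ± 12.9 (SD, n = 2) in stimulated KLF2+ cells and 10.3% ± 3.36 (SD, n = 2) in stimulated KLF2- cells. It was 33.7% ± 14.4 and 18.8% ± 1.02 (SD, n = 2 each) in unstimulated KLF2+ and KLF2- cells. The lowest share, 7.96% (95% Wilson interval 7.95% to 7.97%), was that of stimulated KLF2- replicate 4. The highest was 80.3% (80.3% to 80.3%) in stimulated KLF2+ replicate 2. These intervals cover counting error only.

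Olfactory and vomeronasal receptor genes, which serve smell and have no known role in T cells, measured reads that did not come from spliced transcripts of these cells. Their density ranged from 2.16 reads per kb in stimulated KLF2+ replicate 2 to 8.99 in unstimulated KLF2- replicate 4. At that density, background made up 7.06% and 2.61% of exon reads in unstimulated KLF2+ cells and 1.24% and 0.401% in stimulated KLF2+ cells. It made up 7.80% and 7.09% in unstimulated KLF2- cells, and 11.4% and 20.1% in stimulated KLF2- replicates 3 and 4. TMM factors spanned 0.626 to 1.54. Scaling from genes of at least 50 CPM instead moved the median log2 fold change of all genes from -0.11 to -0.39 for KLF2+ against KLF2- without stimulus, and from -0.19 to -1.39 with stimulus. It moved the median from -0.25 to -0.75 for the KLF2+ response, from 0.06 to 0.45 for the KLF2- response, and from -0.09 to -1.003 for the difference in response. Each comparison is therefore given with and without background correction.

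**Figure D1:**
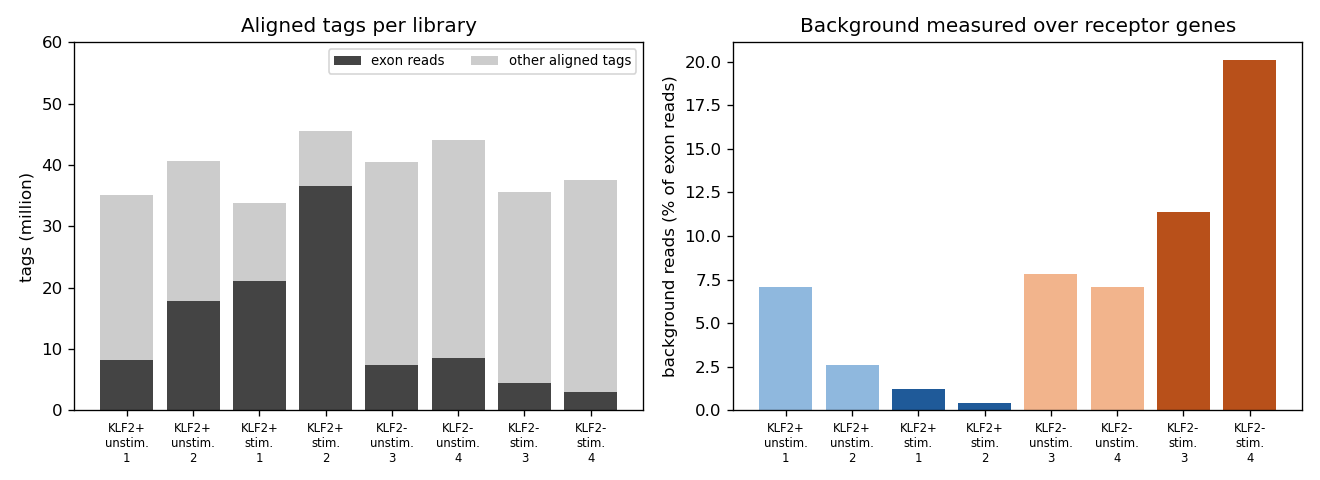
Left, aligned tags per library in M (bars from 0), divided into exon reads and other tags. Right, background reads as a percent of exon reads for the same 8 libraries, from 0.401% in stimulated KLF2+ replicate 2 to 20.1% in stimulated KLF2- replicate 4.

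Klf2 transcript followed the sort in unstimulated cells. Klf2 (mm10 chromosome 8, 72319062 to 72321654) stood at 303 and 379 CPM in the KLF2+ libraries and at 41.0 and 65.0 CPM in the KLF2- libraries. Its log2 fold change was 2.69 ± 0.33 (SE, n = 2 per group; adjusted p = 0.0045 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The same test gave an adjusted p of 0.061 without unstimulated KLF2+ replicate 2 and of 0.086 without unstimulated KLF2- replicate 3, with log2 fold changes of 2.52 and 2.39. Over its 17 alternatives the adjusted p of Klf2 ran from 1.4e-13 to 0.086. Foxp3, the regulatory T cell factor sorted against, was at 11.98 to 16.7 CPM in the unstimulated libraries, with a log2 fold change of 0.32 ± 0.33 (SE, n = 2 per group; edgeR adjusted p = 0.59). Cd4 (log2 fold change 0.46) and Cd44 (0.19) were not called.

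Without stimulus, 10 of 16 genes of the KLF2-linked trafficking list were higher in KLF2+ than in KLF2- cells, 2 were lower and 4 did not pass. Klf2, the gene of the sorted reporter, is a member of the list and among the 10. Its part in the count and in the set tests was fixed by the sort. As sets, this list and the Th17 list passed by camera with its preset correlation, but not with an estimated one (adjusted p = 0.555 and 0.630) or by fry (0.105 and 0.137). Ly6c2 was higher by a log2 fold change of 4.18 ± 0.47 (SE, n = 2 per group) and Cd55, a complement regulator, by 3.44 ± 0.43. S1pr1, the receptor that guides exit into blood and lymph, was higher by 2.27 ± 0.47. In the Th17 list, 7 of 15 genes were lower, 8 did not pass and 0 were higher by edgeR. The cytokine receptor genes Il23r and Il1r1 differed by -2.41 ± 0.35 and -2.15 ± 0.27. Each of these genes had an adjusted p of at most 0.037 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (S1pr1), and both KLF2+ libraries lay on the same side of both KLF2- libraries.

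**Figure D2:**
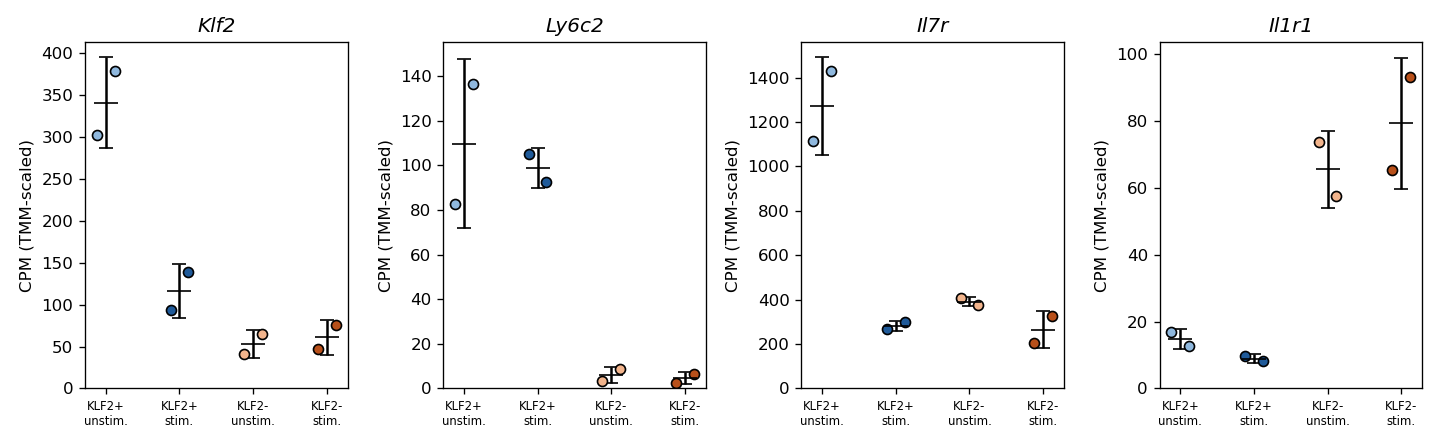
CPM (linear axes from 0) of Klf2, Ly6c2, Il7r and Il1r1 in the 4 groups. Points are libraries, and horizontal marks with bars are the mean and SD of 2 libraries. Klf2, Ly6c2 and Il7r had their highest mean in unstimulated KLF2+ cells, and Il1r1 had its highest mean in stimulated KLF2- cells.

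Other unstimulated differences fell in smaller groups of genes. Of 22 genes of resting and central memory cells, 3 were higher, among them Il7r (log2 fold change 1.70 ± 0.28), the survival cytokine receptor, and Tob1 (1.77 ± 0.26), an antiproliferative gene. In the Tfh list of 19 genes, Tox2 was lower (-3.61 ± 0.23) and Cd40lg, the costimulatory ligand for B cells, was higher (1.11 ± 0.24). The Th2 genes Nfil3 (-2.28 ± 0.40) and Ccr8 (-1.97 ± 0.38) were the 2 lower genes of 15 in that list, and 3 of 16 Treg identity genes were lower, with Tnfrsf9 (-1.44 ± 0.25) and Socs2 (-1.78 ± 0.33) among them. The inhibitory receptor gene Tigit was lower (-2.21 ± 0.34) and Vsir was higher (1.52 ± 0.26), with 15 of that list's 17 tested genes not passing. Trat1, a TCR-associated adaptor, was 1 of 2 higher T cell identity genes of 18 (1.37 ± 0.26). Serpinb9, an inhibitor of granzyme B, was lower (-2.02 ± 0.31) and the other 17 cytotoxic genes did not pass. Suppressive effector molecules divided into 2 higher and 2 lower of 18, with Pdcd1lg2 lower (-2.07 ± 0.27). Th1 genes divided into 3 higher and 1 lower of 18, and 1 of 22 TGF-beta pathway genes was lower. Tgfb1, Il10, Ifng, Il4 and Il2 were not called. Il17a had at most 0.697 CPM in these 4 libraries. Among genes outside the lists, Pxdc1 (-3.69 ± 0.40), the Notch ligand gene Dll1 (-3.81 ± 0.36), Vipr2 (-3.83 ± 0.56), Azin2 (-4.32 ± 0.54) and Insm1 (-4.33 ± 0.72) were the lowest under the naming rule.

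Some markers of other cell types differed between the unstimulated populations, in both directions, while most were not called. Lyz2, the lysozyme of macrophages and neutrophils, stood at 705 and 1376 CPM in unstimulated KLF2+ libraries and at 3.25 and 3.45 CPM in unstimulated KLF2- libraries. Of 22 myeloid markers, 6 were higher and 1 was lower. Csf1r, the macrophage growth factor receptor, was higher by a log2 fold change of 3.52 ± 0.42 and the complement gene C1qb by 6.25 ± 0.81, and Flt3, a receptor of dendritic cells, was lower (-2.18 ± 0.27). Of 17 B cell markers, 3 were higher, with Cd79a at 27.2 and 64.9 CPM against 1.51 and 6.90, while the list summed to less in KLF2+ libraries (1699 and 2270 CPM of exon reads against 2755 and 3095). Klrb1b, an NK receptor gene, was lower (-2.45 ± 0.27), and 1 of 15 NK and innate-like T markers was higher. The 11 erythroid and platelet markers and the 2 CD8 markers tested held 0 calls by edgeR. The genes taken for the largest folds were Lyz2 (log2 fold change 8.27 ± 0.65), Cxcl3 (5.05 ± 0.79), Ly6i (4.74 ± 0.63), Clec4n and Ccl3. Clec4n was at least 260-fold and Ccl3 at least 13.2-fold higher against a floor of 3 counts per library, since the KLF2- libraries held 0 reads.

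In total, 444 of 19146 genes were called between the unstimulated populations, 204 higher and 240 lower in KLF2+ cells, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. After background correction 615 of 15292 genes were called, 149 higher and 466 lower, and 325 were shared with the same direction. Counts of higher and lower genes then were 7 and 2 for trafficking, 0 and 7 for Th17, 1 and 1 for resting memory, 0 and 5 for Tfh, 1 and 6 for inhibitory receptors, 1 and 4 for suppressive effector molecules, 1 and 3 for Treg identity, 2 and 2 for Th1, 1 and 2 for Th2, and 0 and 3 for the TGF-beta pathway by edgeR. They were 1 and 1 for B cell markers and 5 and 1 for myeloid markers. S1pr1 (log2 fold change 1.93 there), Il7r (1.37), Cd40lg (0.77), Cd79a (3.36) and Insm1 (-6.80) were not called there, while Clec4n, Lyz2 and Tox2 were called under all 17 alternatives. The split was 127 higher and 335 lower with scaling from genes of at least 50 CPM, 665 and 483 by DESeq2, 212 and 644 by limma on log2 TPM with a pseudocount of 1, and 190 and 555 with 0.1. Libraries weighed on the count. It was 1897 without unstimulated KLF2+ replicate 1, 33 without replicate 2, 55 without unstimulated KLF2- replicate 3, 58 without replicate 4, and 777 without stimulated KLF2- replicate 4, which enters through the shared spread. Adjusted over the list alone, 15 of 16 trafficking genes (13 higher), 8 of 15 Th17 genes (7 lower) and 11 of 22 resting memory genes (10 higher) passed. By camera, 17 of 30 lists moved as sets. The trafficking list moved up (camera adjusted p = 3.1e-17), and had an adjusted p = 0.555 with an estimated correlation. The Th17 list moved down (camera adjusted p = 7.3e-05), and had an adjusted p = 0.630 with an estimated correlation. With an estimated correlation 0 lists passed, and the smallest adjusted p was 0.208.

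Stimulation of KLF2+ cells raised genes of cell division and metabolism and lowered trafficking genes. All 32 S phase and all 32 G2/M genes rose, among them Mcm10 of the replication origin by a log2 fold change of 4.25 ± 0.29, Uhrf1 by 4.08 ± 0.40, the survivin gene Birc5 by 5.11 ± 0.48 and the kinetochore motor Cenpe by 4.09 ± 0.33 (SE, n = 2 per group). The ubiquitin-conjugating enzyme gene Ube2c rose by 5.86 ± 0.87. Some granzyme and cytokine genes rose with them. The granzyme genes Gzma and Gzmb rose by 7.82 ± 0.94 and 5.76 ± 0.29, and the cytokine genes Il10 by 6.16 ± 0.39, Il21 by 5.63 ± 0.35, Il4 by 4.82 ± 0.43 and Ifng by 2.95 ± 0.38. Klf2 itself fell by 1.55 on the log2 scale (SE 0.32), and 12 of 16 trafficking genes, Klf2 among them, fell and 0 rose. Each of these genes had an adjusted p of at most 0.0076 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

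Among other lists in KLF2+ cells, 17 of 20 glycolysis genes rose and 1 fell (16 and 1 after background correction), with Gapdh up by 2.71 ± 0.34 and Pgk1 by 2.53 ± 0.30. Of 24 cholesterol synthesis genes 22 rose (17 after correction), with Idi1 up by 2.63 ± 0.24 and Fdps by 2.49 ± 0.26. Of 31 oxidative phosphorylation genes 28 rose (26 after correction), Cox5a among them (1.88 ± 0.33). Of 28 ribosome biogenesis genes 24 rose (16 up and 1 down after correction), Npm1 among them (2.24 ± 0.39). Of 24 amino acid and one-carbon genes 18 rose and 1 fell (10 and 1 after correction), and 16 of 21 unfolded protein response genes rose (14 after correction), with Pdia6 up by 1.94 ± 0.26. Replication-dependent histone genes rose in 8 of 12 (6 of 9 after correction), p53 and apoptosis genes rose in 10 of 22 and fell in 3 (6 and 3 after correction), and heat-shock stress genes rose in 6 of 16 (5 up and 1 down after correction). Of 34 interferon-stimulated genes 7 rose and 5 fell (1 and 6 after background correction, where the list's median went from 0.35 to -0.12), with Gbp2 up by 2.20 ± 0.33 and Ifit2 changed by -1.08 ± 0.22.

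Lists of T cell programs held rising and falling genes in KLF2+ cells. Of 31 early TCR response genes 18 rose and 1 fell (13 and 1 after correction), among them the transcription factor genes Nr4a1 (2.94 ± 0.31), Egr2 (3.17 ± 0.34) and Batf (2.32 ± 0.24). Of 15 Th2 genes 11 rose (8 up and 1 down after correction), with Ccr8 (5.26 ± 0.41) and Nfil3 (4.38 ± 0.44) beside Il4, and 7 of 18 Th1 genes rose and 2 fell (5 and 5 after background correction, median 0.42 and then -0.10), with Il12rb2 (4.76 ± 0.29) beside Ifng. Of 19 Tfh genes 9 rose and 1 fell (8 and 3 after correction), with Tox2 (3.05 ± 0.23) beside Il21. Of 16 Treg identity genes 11 rose and 2 fell (7 and 2 after correction), with the costimulatory and checkpoint receptor genes Tnfrsf9 (3.02 ± 0.26), Tnfrsf4 (3.87 ± 0.48) and Ctla4 (2.88 ± 0.34), while Foxp3 was not called (0.44 ± 0.32). Suppressive effector molecules rose in 10 of 18 and fell in 2 (8 and 2 after correction), cytokines rose in 15 of 31 (10 up and 3 down after correction), and cytotoxic genes rose in 6 of 18 and fell in 1 (4 and 2 after correction). T cell identity genes rose in 1 of 18, and after correction 1 rose and 5 fell, with the median going from 0.24 to -0.29. TGF-beta pathway genes rose in 4 of 22 and fell in 4 (1 and 5 after correction). Inhibitory receptors rose in 8 of 17 and fell in 3 (6 and 3 after correction), with Tigit (3.63 ± 0.35) and Lag3 (4.25 ± 0.55) among them. Tgfb1, the gene of the cytokine TGF-beta 1, rose by 1.24 ± 0.37 and was not called after background correction (edgeR adjusted p = 0.15). Resting and central memory genes fell in 12 of 22 and rose in 3 (17 and 0 after correction by edgeR), with Il7r changed by -2.17 ± 0.28. Klf3 (-1.80 ± 0.23), Itga4 (-1.73 ± 0.26) and Rasgrp2 (-1.71 ± 0.29) fell among the trafficking genes, as did S1pr1 (-1.85 ± 0.46). Il2 was not called (-1.64 ± 0.61), but was lower and called in 10 of its 18 alternatives (log2 fold change from -2.30 to -1.39). Akr1c18 (6.78 ± 0.64) and Tnfrsf8 (6.00 ± 0.48), which encodes CD30, completed the largest changes. Myeloid markers fell in 20 of 22 (16 after correction), with Lyz2 changed by -4.48 ± 0.53 and Csf1r by -3.83 ± 0.42, as did the mast cell protease gene Prss34 (-5.41 ± 0.49). Slc7a14 (-4.31 ± 1.02), Adcy1 (-4.38 ± 1.02) and Shisal1 (-5.08 ± 0.95) also fell. Shisal1 held 23.4 CPM in unstimulated KLF2+ replicate 1 and 2.58 in replicate 2, the libraries with 7.06% and 2.61% background.

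In the KLF2+ response, 7096 of 19146 genes were called, 3771 higher and 3325 lower after stimulus, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. After background correction 4447 genes were called, 1937 higher and 2510 lower, with 3471 shared in the same direction. Before correction 139 of 486 receptor genes were called, and after it 49 of 268, with a median log2 fold change of -2.51. The lower calls may therefore still hold genes at background level after correction. Then 32 G2/M and 29 S phase genes were higher and 13 trafficking genes lower, and Slc7a14 was not called. The split was 2167 higher and 5667 lower with scaling from genes of at least 50 CPM, 1557 and 3112 by limma on log2 TPM with a pseudocount of 1, and 1751 and 6069 with 0.1. The count was 2323 without unstimulated KLF2+ replicate 1 and 2506 without stimulated KLF2+ replicate 2. By camera 24 of 30 lists moved as sets, with G2/M up (camera adjusted p = 3.1e-37) at an adjusted p = 0.213 with an estimated correlation. With an estimated correlation 0 lists passed, and the smallest adjusted p was 0.127. Adjusted over the list alone, 24 of 24 cholesterol genes, 17 of 22 resting memory genes and 12 of 16 trafficking genes passed.

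In KLF2- cells the 2 stimulated libraries differed from each other, and edgeR's quasi-likelihood test on the 8 libraries gave 0 calls for the response (2802 genes at an unadjusted p under 0.05, 74 by DESeq2 and 770 with a replicate block). Top2a, the topoisomerase of dividing cells, stood at 219 CPM in stimulated KLF2- replicate 3 and 40.5 CPM in replicate 4, against 49.4 and 44.4 CPM in the unstimulated libraries. Its log2 fold change was 1.47 ± 0.58 (SE, n = 2 per group; edgeR adjusted p = 0.30). The summed level of the G2/M list after background subtraction was 3006 CPM in replicate 3, 725 CPM in replicate 4, and 554 and 535 CPM without stimulus. Mcm6 of the replication helicase stood at 297 and 146 CPM in replicates 3 and 4 against 225 and 217 CPM unstimulated, and its log2 fold change of 0.01 ± 0.32 averages libraries on opposite sides. The S phase list after background subtraction summed to 4254 and 1450 CPM against 1705 and 1553 CPM. The most abundant members of other lists were not called. The glycolytic gene Ldha differed by 0.16 ± 0.42, Srebf2 of the cholesterol list by 0.01 ± 0.22, Ncl of ribosome biogenesis by -0.11 ± 0.32 and Gzmb by 0.28 ± 0.27. Itgb1 of the trafficking list (-0.21 ± 0.37), Ets1 (-0.40 ± 0.26) and Nfkbia (-0.25 ± 0.28) were likewise not called, nor was Klf2 (0.20 ± 0.32) or any other gene that was always read.

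**Figure D3:**
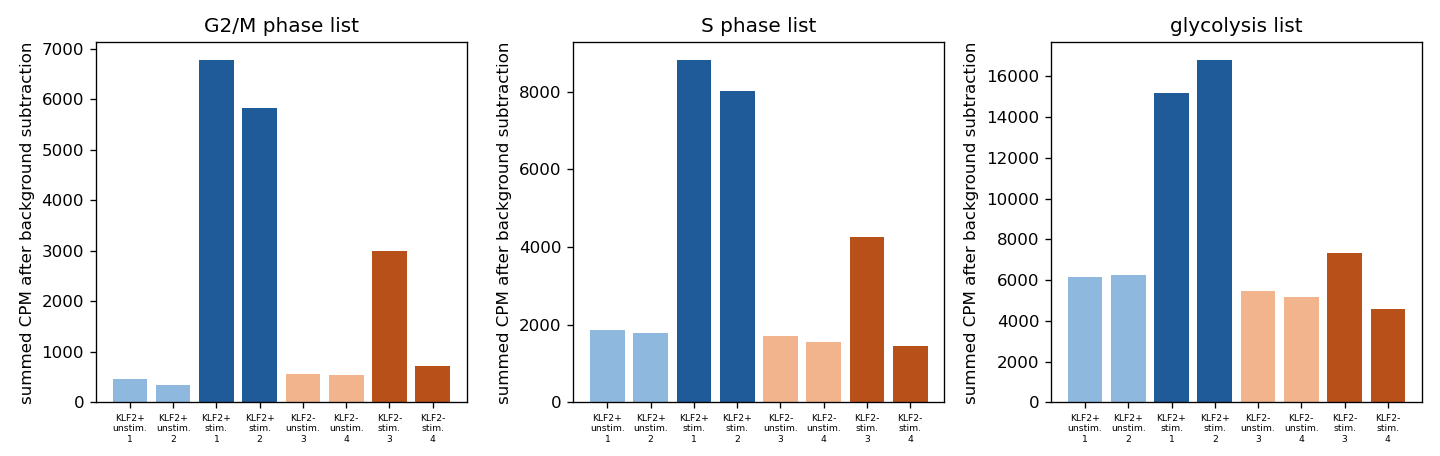
Summed CPM after background subtraction of the G2/M, S phase and glycolysis lists in each library (bars from 0). Stimulated KLF2- replicate 3 stood at 3006 CPM for G2/M, and replicate 4 at 725, near the 4 unstimulated libraries.

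The KLF2- response had 0 called genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2802 genes at an unadjusted p under 0.05, and 74 calls by DESeq2. With the replicate number as a block, 770 genes were called, 311 higher and 459 lower, though the labels do not say that the numbers pair the libraries. Without stimulated KLF2- replicate 4, 107 genes were called, 102 higher and 5 lower, including 24 of 32 G2/M and 14 of 32 S phase genes. The lone stimulated library was there assumed to vary like the other groups. With background correction as well, 392 genes were called, 273 higher and 119 lower. Without replicate 3 there were 42 calls, 2 higher and 40 lower. Adjusted over the list alone, 24 of 32 G2/M genes were higher and 7 of 34 interferon-stimulated genes were lower in the 8 libraries. By camera 14 of 30 lists moved as sets, with G2/M up (camera adjusted p = 1.5e-15) at an adjusted p = 0.904 with an estimated correlation, which was also the smallest.

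With stimulus, KLF2+ cells stood above KLF2- cells in the division and metabolic lists and in single granzyme and cytokine genes. Folds for this comparison are from the fit without background correction unless stated. In that fit genes of at least 50 CPM had a median log2 fold change of 1.18. It was -0.02 after correction, which is scaled from such genes. Gzmb stood at 835 ± 74.1 CPM in KLF2+ cells and 12.6 ± 3.10 CPM in KLF2- cells (SD, n = 2 each), a log2 fold change of 6.03 ± 0.30 (SE). Gzma was higher by 6.15 ± 0.87, Il21, a cytokine of follicular help, by 6.23 ± 0.38, the anti-inflammatory cytokine gene Il10 by 4.31 ± 0.36, Ifng by 3.50 ± 0.40 and Il4 by 3.26 ± 0.40. Il1r1 (-3.15 ± 0.28) was lower, with 8 of 15 Th17 genes lower and 3 higher, including Batf (3.06 ± 0.25). As a set the Th17 list did not pass before correction (camera adjusted p = 0.200, fry 0.0570) and passed by camera after it (adjusted p = 0.0019, 8 lower and 1 higher) but not with an estimated correlation (adjusted p = 0.296). Cytotoxic genes were higher in 10 and lower in 2 of 18 (5 and 4 after correction), and cytokines were higher in 19 of 31 (10 higher and 5 lower after correction). The genes with a fold change in this paragraph had adjusted p-values of at most 4.1e-04 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and were called in the same direction after background correction.

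**Figure D4:**
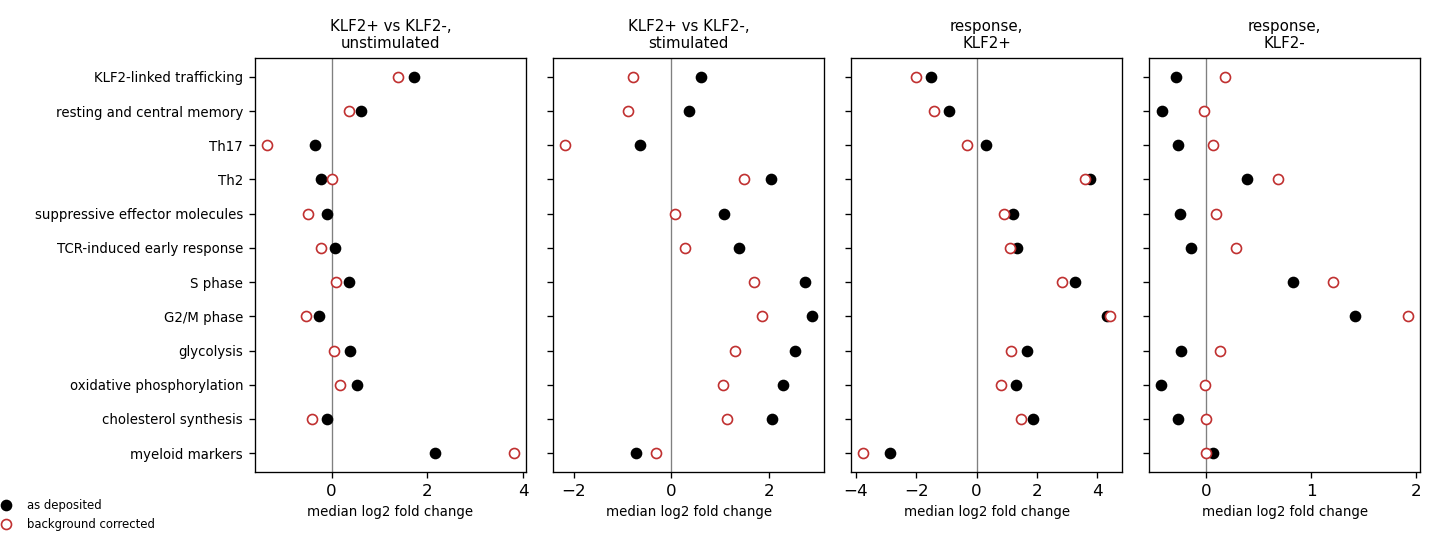
Median log2 fold change (x axes) of 12 gene lists in the 4 comparisons between groups. Filled points are from the counts as deposited and open points from background-corrected counts. In the stimulated comparison the S phase and G2/M medians were 2.75 and 2.88 as deposited, 1.70 and 1.86 after correction, and 1.10 and 1.16 after correction without stimulated KLF2- replicate 4.

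All 32 S phase and 32 G2/M genes were higher in stimulated KLF2+ cells, and after background correction 23 and 21 of them were. Mcm10 was higher by 2.29 ± 0.27, the replication factor gene Rfc2 by 2.33 ± 0.28, Cdca3 by 3.46 ± 0.45 and the mitotic kinase gene Cdk1 by 3.05 ± 0.44. Over 16 alternatives Mcm10 ran from 0.85 to 2.76, Rfc2 from 0.90 to 2.73, Cdca3 from 1.77 to 4.65 and Cdk1 from 1.44 to 4.12. Glycolysis genes were higher in 18 of 20 (15 after correction), with Tpi1 at 3.94 ± 0.46 and Pgk1 at 3.26 ± 0.31. Oxidative phosphorylation was higher in 31 of 31 (27 after correction), cholesterol synthesis in 23 of 24 (17 after correction) with Fdps at 2.99 ± 0.27, and ribosome biogenesis in 27 of 28 (20 after correction). The unfolded protein response was higher in 19 of 21 and lower in 1 (12 and 3 after correction), with Creld2 at 2.88 ± 0.28. Stimulated KLF2- replicate 4 lay near the unstimulated libraries in the division lists, and without it 32 S phase and 30 G2/M genes were higher.

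Of 18 Th1 genes 13 were higher (8 higher and 4 lower after correction), with Il12rb2 at 3.43 ± 0.27 and Ccl4 at 4.08 ± 0.38, and of 15 Th2 genes 11 were higher (6 higher and 1 lower after correction), with Pparg at 3.37 ± 0.34 and Nfil3 at 2.92 ± 0.41. Of 16 Treg identity genes 10 were higher and 4 lower (6 and 4 after correction), with Ctla4 at 3.83 ± 0.36 and Tnfrsf4 at 3.36 ± 0.47. Of 18 suppressive effector molecules 11 were higher and 1 lower (6 and 3 after correction), with the transcription factor gene Prdm1 at 2.52 ± 0.22 and Ebi3 at 2.97 ± 0.29. Tigit was higher by 3.28 ± 0.36, Gbp2 by 3.32 ± 0.34, Ifitm3 by 6.44 ± 0.33, Ccl3 by 5.77 ± 0.78 and the chaperone gene Hsp90aa1 by 3.15 ± 0.33. T cell identity genes were higher in 17 of 18, with Cd2 at 2.72 ± 0.34, and after background correction 4 were higher and 3 lower. The early TCR response list had 24 of 31 genes higher, and after correction 4 higher and 6 lower. Trafficking genes were higher in 7 and lower in 2 of 16, and after correction higher in 2, Ly6c2 (4.47 ± 0.50 before correction) among them, and lower in 6. Resting memory genes were higher in 9 and lower in 2 of 22, and after correction 0 were higher by edgeR and 15 were lower.

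Several reference genes changed direction with the scaling. Klf2 had a log2 fold change of 0.93 ± 0.32 in stimulated KLF2+ against KLF2- cells, and -0.39 ± 0.37 after background correction (edgeR adjusted p = 0.024 and 0.40). Cd4 had 0.73 ± 0.24 and, after correction, -0.60 ± 0.15 (adjusted p = 0.018 and 0.015 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Cd44 had 0.12 ± 0.22 and then -1.17 ± 0.24, and Tgfb1 1.38 ± 0.38 and then 0.23. Tgfb1 was below 0 by limma on log2 TPM. Foxp3 was at 20.4 and 21.3 CPM in KLF2+ and 8.57 and 5.23 CPM in KLF2- libraries, a called difference of 1.58 ± 0.34 that was not called after correction (edgeR adjusted p = 0.094). S1pr1 was not called, and Il2 was not called by edgeR's test with TMM factors (log2 fold change -1.47, adjusted p = 0.052) but was lower and called in 11 of its 16 alternatives (log2 fold change from -3.22 to -0.26, adjusted p from 0.0010 to 0.72). Of 17 B cell markers 4 were higher and 2 lower, and after correction 4 were higher and 7 lower of 16, with the median going from -0.22 to -1.24. Lyz2 was higher (3.16 ± 0.56) and Flt3 lower (-3.19 ± 0.29), with 3 of 22 myeloid markers higher and 8 lower, and Klrb1b was lower (-3.29 ± 0.29), with 7 of 15 NK and innate-like markers lower. The lowest genes under the naming rule were Stc1 (-5.92 ± 0.74), Krt75 (-5.97 ± 0.90), Scn4b (-6.40 ± 1.06), Shisal1 (-6.88 ± 0.98) and Lrrc8e (-7.05 ± 1.01). Each of the 5 had its highest level in stimulated KLF2- replicate 4, the library with 20.1% background, and Shisal1 stood at 52.7 CPM there and at 0.453 and 0.305 CPM in stimulated KLF2+ cells.

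Between the stimulated populations 14396 of 19146 genes were called, 6799 higher and 7597 lower in KLF2+ cells, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of 486 receptor genes tested, 396 were called, with a median log2 fold change of -3.10. After background correction 8338 genes were called, 2441 higher and 5897 lower, with 6322 shared in the same direction. Of 268 receptor genes tested there, 190 were still called, with a median of -4.41, so the lower calls hold genes at background level. These 268, of the 1464 that measured background, passed the filter on reads left after subtraction. Their direction and median are shaped by that selection and do not measure how far the correction worked over all genes. With 2 times the background subtracted 5918 genes were called. The split was 2280 higher and 11169 lower with scaling from genes of at least 50 CPM, 1791 and 12299 by limma on log2 TPM with a pseudocount of 1, and 1776 and 12433 with 0.1. Without stimulated KLF2- replicate 4, 11681 genes were called. By camera 22 of 30 lists moved as sets, with oxidative phosphorylation up (camera adjusted p = 2.0e-12) at an adjusted p = 0.340 with an estimated correlation, the smallest of the 30. Adjusted over the list alone, 20 of 20 glycolysis genes passed, 19 of them higher.

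Among the 19146 genes, 312 were called in the same direction between populations without and with stimulus, 144 higher and 168 lower in KLF2+ cells, where independent lists of those sizes share 72.4 and 95.2. The 2 comparisons share no library, but independence cannot be assumed for them. Mean background was higher in KLF2- cells in both states (7.44% against 4.84% and 15.7% against 0.820%). Without stimulus that gap came mostly from KLF2+ replicate 2 (2.61%), since replicate 1 had 7.06% against 7.80% and 7.09%. Same-numbered KLF2+ libraries deviated alike (r = 0.537, and 0.375 after background correction). A further 27 were called in opposite directions. After background correction 458 were shared, 90 higher and 368 lower, against 23.8 and 179.7 for independent lists. The count in the same direction was 1669 without unstimulated KLF2+ replicate 1, 23 without replicate 2, 44 without unstimulated KLF2- replicate 3 and 46 without replicate 4. It was 473 without stimulated KLF2- replicate 3 and 553 without replicate 4. Ly6c2 was higher, and Il1r1, Flt3 and Klrb1b were lower, in both. The 2 stimulation responses shared 0 calls because the KLF2- response had none by edgeR, with 2802 genes there at an unadjusted p under 0.05 and 74 DESeq2 calls.

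Granzyme and cytokine genes were among those whose response to stimulus differed between the populations. The difference in response, KLF2+ minus KLF2-, was 9.18 ± 1.19 on the log2 scale (SE) for Gzma, 6.05 ± 0.61 for Tnfrsf8, 5.99 ± 0.52 for Il21, 5.81 ± 0.62 for Ecm1 and 5.49 ± 0.49 for Tigit. Tigit stood at 3.60 and 5.57 CPM in unstimulated and 50.8 and 64.6 CPM in stimulated KLF2+ libraries, against 21.4 and 21.7 and then 7.58 and 4.14 CPM in KLF2- libraries. Gzmb (5.48 ± 0.38), Il10 (4.83 ± 0.55), Il4 (4.43 ± 0.57) and Ifng (4.00 ± 0.53) differed in the same direction, as did Nfil3 (5.20 ± 0.57), Ccr8 (4.10 ± 0.52), Il12rb2 (4.90 ± 0.38), Ctla4 (3.45 ± 0.47), Tnfrsf9 (3.65 ± 0.36) and Batf (2.75 ± 0.34). Klf2 (-1.75 ± 0.45), Il7r (-1.61 ± 0.39), Rasgrp2 (-1.86 ± 0.42) and Il2 (-2.97 ± 0.87) differed in the opposite direction. These genes had adjusted p-values of at most 0.032 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

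By list, the difference in response was called positive for 31 of 32 G2/M genes, with Birc5 at 4.02 ± 0.60, and for 27 of 32 S phase genes. It was called positive for 18 of 20 glycolysis genes, with Pgk1 at 2.65 ± 0.42, and for 22 of 24 cholesterol genes, with Idi1 at 3.33 ± 0.33. After background correction the counts of called genes were 3, 4, 8 and 12, while the medians of the lists were 2.29, 1.52, 1.16 and 1.56 against 2.95, 2.37, 1.95 and 2.04 before. Without stimulated KLF2- replicate 4 they were 29, 29, 16 and 19. The difference was called negative for 13 of 22 myeloid markers, with Lyz2 at -5.11 ± 0.80 and Csf1r at -4.42 ± 0.58, and for 7 of 16 trafficking genes. Without stimulated KLF2- replicate 4 it was negative for 9 myeloid markers and 2 trafficking genes, and after background correction for 9 and 10. Clec4n, whose unstimulated KLF2- libraries held 0 reads, had a fitted value of -7.89 that depends on the prior count. Prss34 (-5.27 ± 0.62), Scn4b (-5.30 ± 1.30), Slc7a14 (-5.36 ± 1.31) and Shisal1 (-5.77 ± 1.18) were the other lowest genes.

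In all, 6855 of 19146 genes were called for the difference in response, 3890 positive and 2965 negative, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. After background correction 1807 were called, 547 positive and 1260 negative, 1409 of them shared with the same direction. Before correction 145 of 486 receptor genes were called, and after it 33 of 268, with a median of -3.76. The negative calls may therefore still hold genes at background level after correction. Il21 (11.91 ± 3.73 there), Il2 (-3.91 ± 1.05), Scn4b (-10.62 ± 3.04), Slc7a14 (-10.82 ± 3.21) and Shisal1 (-11.07 ± 3.44) were not called there. Their standard errors were derived from the folds and F. For Il21, Scn4b, Slc7a14 and Shisal1 they grew more than the folds did, so F was lower there. For Il2 the standard error grew less than the fold, and why its call was lost was not tested. The larger of these folds may depend on the prior count, as for Clec4n, which was not tested. Clec4n was not called there either. Over 20 alternatives Il21 ran from 4.04 to 11.99 and Il2 from -4.57 to -1.76. The split was 1017 and 5102 with scaling from genes of at least 50 CPM, 2705 and 3266 with RLE factors, 3110 and 3683 by DESeq2, 813 and 4808 by limma on log2 TPM with a pseudocount of 1, and 850 and 5493 with 0.1. The count was 553 without unstimulated KLF2+ replicate 1, 1890 without stimulated KLF2+ replicate 2, 64 without unstimulated KLF2- replicate 3, 57 without replicate 4 and 2507 without stimulated KLF2- replicate 4. By camera 24 of 30 lists moved as sets, and the smallest adjusted p was 0.248 with an estimated correlation.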

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

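The tests of explanations given here were chosen only after the results were seen. The results listed first were tested directly as a difference between the populations in their response to stimulus.

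Under the same contrast, stimulated against unstimulated, 6855 genes differed in response between KLF2+ and KLF2- cells by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Simulated equal expression with the measured background added gave 5377 of 22942 genes, so much of this count could come from background, and it was 1807 after background correction and 2507 without stimulated KLF2- replicate 4. It was 553 without unstimulated KLF2+ replicate 1, 1890 without stimulated KLF2+ replicate 2, and 64 and 57 without unstimulated KLF2- replicates 3 and 4. The log2 difference in response, KLF2+ minus KLF2-, was 9.18 for Gzma, 6.05 for Tnfrsf8, 5.99 for Il21, 5.81 for Ecm1 and 5.49 for Tigit. It was 5.48 for Gzmb, 5.20 for Nfil3, 4.90 for Il12rb2, 4.83 for Il10, 4.43 for Il4, 4.10 for Ccr8, 4.02 for Birc5 and 4.00 for Ifng. It was 3.65 for Tnfrsf9, 3.45 for Ctla4, 3.33 for Idi1, 2.75 for Batf and 2.65 for Pgk1. It was -1.61 for Il7r, -1.75 for Klf2, -1.86 for Rasgrp2, -2.97 for Il2, -4.42 for Csf1r and -5.11 for Lyz2. The lowest values were -5.27 for Prss34, -5.30 for Scn4b, -5.36 for Slc7a14, -5.77 for Shisal1 and -7.89 for Clec4n, of which Clec4n had 0 reads in 1 group. After background correction Clec4n, Scn4b (-10.62 ± 3.04), Slc7a14 (-10.82 ± 3.21), Shisal1 (-11.07 ± 3.44), Il21 (11.91 ± 3.73) and Il2 (-3.91 ± 1.05) were not called. For the 5 with a value here the standard error before correction was 1.30, 1.31, 1.18, 0.52 and 0.87. Each standard error was derived from the fold and F. For Scn4b, Slc7a14, Shisal1 and Il21 it grew more than the fold did, so F was lower after correction. For Il2 it grew less than the fold, and why that call was lost was not tested. The larger of these folds may depend on the prior count, as for Clec4n, which was not tested.

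Stimulated KLF2- replicate 4 lacked the division transcripts of the other 3 stimulated libraries. Dilution by background reads was argued against, since its G2/M level after background subtraction was 24.1% of that of replicate 3. An exchange with an unstimulated library was argued against too, since the highest G2/M level among the 4 unstimulated libraries was 18.4% of the lowest among the other 3 stimulated ones. A single unstimulated KLF2- library under a wrong label cannot be told apart from a weak response: 4 of 25 early TCR response genes (Egr1, Egr2, Nr4a1 and Nr4a2) were at least 2-fold above both unstimulated KLF2- libraries, 16.0% against 11.1% of 9887 other genes (one-sided Fisher exact p = 0.301), where replicate 3 gave 5 of 25 and 4.09% (p = 0.0031). A failed or weaker culture stays open as well, and the design gives no biological explanation to test within 1 group.

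The 14396 genes called between the stimulated populations may in part rest on background reads: with equal expression simulated in all libraries and the measured background added, the same model called 14085 of 22942 genes, against 14396 of 19146 here. Of 58 genes of other tissues that had no part in measuring background, 40 (69.0%) were called lower in KLF2+ cells and 0 higher by edgeR. The 58 were defensins, taste receptors, hair keratin-associated, major urinary, pregnancy-specific and placental prolactin genes. After correction 17 of 23 were still called lower. Genes at background level pass the expression filter mainly through the group with most background, stimulated KLF2- cells. Their direction was thus largely set in advance, and the count adds no separate evidence. Genes of at least 50 CPM had a median log2 fold change of 1.18 in the fit without correction, as scaling factors pulled by background reads would give, though a true difference in most of these genes would give it too. Background was argued against as the whole cause for the S phase, G2/M and glycolysis lists, where 59 of 84 genes (70.2%) were still called higher in KLF2+ cells after correction. For these lists a difference between the sorted populations stays open beside the state of stimulated KLF2- replicate 4, without which 32 S phase and 30 G2/M genes were higher before correction and 28 and 21 after it.

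Some myeloid transcripts were higher in unstimulated KLF2+ libraries, with 6 of 22 markers called higher and 1 lower. The list summed to 1688.5 and 2344.8 CPM of exon reads there, against 1211.1 and 1218.1 in unstimulated KLF2- libraries. That gap was no larger than the level of Lyz2 alone. Fcer1g (-0.48), Spi1 (-0.39) and Cst3 (-1.54) had negative log2 fold changes and were not called. Background reads were argued against, since they would move the 22 myeloid markers as they moved 486 receptor genes. The medians were 2.15 and -0.32 on the log2 scale (one-sided permutation p = 1e-05, the smallest that 100000 permutations can give). The argument rests on the medians and not on that p. The list was taken up for its high values, and genes were shuffled as if independent. A lower share of T cells, with the mix of other cells unchanged, would raise markers of every other type alike. It was argued against in that form only. The 28 markers of other types of at least 10 CPM moved apart by more than their standard errors (Cochran Q of 612 on 27 degrees of freedom). The Cochran Q heterogeneity p was 7.9e-112, with 5 called higher and 2 lower, Flt3 and Klrb1b. That p takes genes as independent, with standard errors from 2 libraries per group. Some of the markers, such as Il2rb of the Treg identity list, can come from T cells and would move apart anyway. A changed mix of other cells was not tested. Myeloid and B cell medians alone did not separate (permutation p = 0.0667). Myeloid cells passing a sort for CD4, which should remove most of them, are a candidate source that stays open, with 14 of 22 markers (63.6%) over a log2 fold change of 1, and 0 genes of the list in another list. Of its most abundant genes Lyz2 stood at 705 and 1376 CPM against 3.25 and 3.45 in unstimulated KLF2- cells, Ctss at 359 and 667 against 266 and 272, and Cst3 at 151 and 206 against 503 and 537, and expression of these genes by the T cells was not tested.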

How the results depend on the processing

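The alternatives that subtract background, rescale from genes of at least 50 CPM, or leave out stimulated KLF2- replicate 4 from every comparison were chosen after seeing the data, and the others were planned. Klf2 kept its direction between unstimulated populations in all 17 alternatives, and the other values below moved. Where no cause is named, the cause was not tested. Genes called between unstimulated populations (444) numbered 1148 by DESeq2, 856 and 745 by limma on log2 TPM with pseudocounts of 1 and 0.1, 828 in the 4 libraries alone, and 1481 with background correction without stimulated KLF2- replicate 4. Between stimulated populations (14396) they numbered 8974 with background subtracted, 8338 after rescaling as well, 5918 with 2 times the background, and 7012 with the correction without stimulated KLF2- replicate 4. The KLF2+ response (7096) had 4669 by limma with a pseudocount of 1, 4414 with background subtracted, 4447 after rescaling, and 3148 with 2 times the background. The KLF2- response (0 by edgeR, 2802 at an unadjusted p under 0.05) had 74 by DESeq2, 2 with no filter, 3 and 5 by limma with pseudocounts of 1 and 0.1, and 392 with the correction without stimulated KLF2- replicate 4. The difference in response (6855) had 2245 with background subtracted, 1807 after rescaling, 453 with 2 times the background, and 1129 with the correction without stimulated KLF2- replicate 4. Genes called in the same direction in both states (312) numbered 877 by DESeq2 and 960 with the correction without stimulated KLF2- replicate 4. Of 150 tests of lists, 101 passed by camera, 0 with an estimated correlation, 70 by fry, and 59 with 2 times the background. The labels number libraries alike across the 2 states of a population but do not say that the numbers pair them. Deviations of same-numbered libraries correlated at 0.537 in KLF2+ and 0.0865 in KLF2- cells over genes. With the number as a replicate block, the calls rose to 10851 for the KLF2+ response, 770 for the KLF2- response and 10857 for the difference in response. Of the 150 list tests 100 then passed. The 2 comparisons between populations, which the block cannot test, entered that count with their results without it. Leaving out 1 library gave 33 to 1897 calls without stimulus, 7012 to 13408 with stimulus (11535 the lowest of those without correction), 2323 to 9032 for the KLF2+ response, 0 to 392 for the KLF2- response (107 the highest without correction), 57 to 9609 for the difference in response, and 23 to 1669 for the shared direction. Over the same fits Klf2 without stimulus had a log2 fold change of 2.39 to 3.06. A group with 1 library left was there assumed to vary like the others. Lists were tested again only without stimulated KLF2- replicate 4, so their dependence on the other libraries was not measured.

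Between stimulated populations, the direction of 4 reference genes given here turned. Klf2 (0.93) was at -0.49 and -0.50 by limma with pseudocounts of 1 and 0.1, -0.30 with scaling from genes of at least 50 CPM, -0.39 after background correction, and -0.44 with 2 times the background. Cd4 (0.73) was at -0.71 by limma with either pseudocount, -0.045 with background subtracted, -0.47 with the rescaling alone, -0.60 after correction, -0.70 with 2 times the background, and -0.42 after correction without stimulated KLF2- replicate 4. Cd44 (0.12) was at -1.27 and -1.31 by limma, -0.61 with background subtracted, -1.10 with the rescaling alone, -1.17 after correction, -1.20 with 2 times the background, and -0.77 after correction without stimulated KLF2- replicate 4. Tgfb1 (1.38) was at -0.0637 and -0.0673 by limma and at -0.12 after correction without stimulated KLF2- replicate 4. For the difference in response, Cd4 (0.27) was at -0.79 and -0.80 by limma. Rescaling alone moved the median log2 fold change of all genes between the stimulated populations from -0.19 to -1.39. Many small changes would be missed in such data. In counts simulated at the same depths, 12 of 100 changes of 2-fold and 57 of 100 of 4-fold were recovered for the KLF2- response. For the KLF2+ response 14 and 62 were recovered. The simulation gave all groups 1 mean profile, 1 shared trend of spread and no difference in background. It therefore cannot compare power between the populations. After background correction, the stimulated KLF2- libraries correlated at 0.846 with each other and the stimulated KLF2+ libraries at 0.982.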

Other observations

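The readings of Il2ra, Irf4, Myc, Nr4a1 and Egr1 were chosen only after their values were seen. The 2 stimulated KLF2- libraries differed in these genes of T cell activation. After background subtraction, Il2ra, the high-affinity receptor chain for interleukin 2, stood at 513 CPM in replicate 3 and 42.9 CPM in replicate 4, against 57.7 and 46.6 CPM in unstimulated KLF2- cells. Irf4, a transcription factor of activated T cells, stood at 112 and 6.66 CPM against 15.6 and 13.9, and Myc at 124 and 13.7 CPM against 82.5 and 55.7. Nr4a1, an early response gene of TCR signalling, stood at 49.3 and 85.8 CPM against 6.68 and 5.93, and Egr1 at 147 and 67.05 CPM against 28.7 and 27.2. In stimulated KLF2+ cells Il2ra stood at 768 and 935 CPM and Nr4a1 at 62.3 and 119 CPM.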
